A study of Mycolicibacterium smegmatis MC2 155 with 6 samples.

How the data were processed

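The sources used here describe membrane-fraction RNA of *M. smegmatis* MC2 155 from 3 libraries of active and 3 of dormant ovoid cells. Per the labels' protocols, cells were lysed by bead beating, the membrane fraction was pelleted and washed by ultracentrifugation, and RNA was extracted with phenol-chloroform, treated with Turbo DNase and made into strand-specific libraries with a NEBNext directional kit. The protocols mention no step that removes rRNA. The deposited values are raw counts per locus tag, made by the authors by aligning reads with Bowtie2 and counting them with featureCounts, per the submitters' processing notes. The versions, options, strand setting, treatment of multiply mapped reads and genome build are not given in the sources used here. A gene that overlaps another on the opposite strand can therefore hold reads of its neighbour, and counts of near-identical genes can be shared: the rRNA copies and the *nrdE* copies had almost equal counts in each library.

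The table of the whole series and the 6 tables of single libraries held the same counts, with 0 differing cells and 0 columns left unmapped. Of 6938 rows, 6566 matched a locus tag in the RefSeq annotation of assembly ASM1500v1, 372 did not, and 1004 had a gene symbol. That annotation was used for symbols, gene types and neighbourhood only, and no coordinates or lengths are given because the build behind the counts is not named. For the same reason the planned correlation of counts with gene length was not run. As planned, 6 rRNA rows were left out of library sizes and tests. The 47 tRNA rows were kept.

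Totals ranged from 5333195 to 14690576 counts per library. Shares of single libraries have exact (Clopper-Pearson) 95% intervals from scipy 1.17.1. These were no wider than 0.0577 percentage points for rRNA, and of the *ssrA* shares the widest interval was 44.7% to 45.1% in dormant replicate 9. For a single library, a count of 0 allows up to 3 counts. Both cover counting error only, since reads without molecular identifiers are not independent molecules. The main comparison used edgeR 4.0.16 in R 4.3.3 with TMM factors, the filterByExpr filter and the quasi-likelihood F-test without covariates, because the groups share no replicate numbers. It tested 6033 genes, with a common biological coefficient of variation of 0.645, and called genes at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the fold change divided by the square root of the F statistic. CPM values are TMM-normalised on counts outside rRNA. Gene lists of at least 3 tested genes were compared with the other genes by camera in limma 3.58.1 with a preset correlation of 0.01, beside an estimated correlation and the fry test, with adjustment over 25 lists. Shares and numbers of detected genes were compared by exact two-sided permutation tests over all splits of the libraries, where 3 against 3 libraries cannot give a p below 0.1.

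The rule for named genes was fixed before the data were examined. It takes the 6 called genes with the largest rise and the 6 with the largest fall, given a mean of at least 50 counts, an absolute log2 fold change of at least 1 and no overlap of the groups. From each list it takes the called members with the largest rise and fall, or the 2 with the highest mean count where none is called. It adds a panel of 12 genes linked to dormancy. It named 64 genes. Other genes, among them the rest of the 12 called, *ssrA*, the genes of runs and further list members such as *clpB*, *lon*, *msrB*, *rpsS*, *rpsM*, *rplT*, *trpS*, *pheS*, *murC*, *treZ*, *otsB*, *groL*, *mbtM*, *cydB*, *ctaC*, *hemB*, *ripA* and *ripB*, were chosen after their values were seen. Panel genes without a symbol in the annotation carry the names given to their locus tags in the plan. The lists were planned from locus tags and product names, and the plan was to use the tags alone where product names were lacking. The annotation gave no product names. In a departure from the plan, the lists were extended with gene symbols after the annotation was seen and before any test, and lists from the planned tags alone (13 of them testable) were run beside them. The rule for named genes was applied to the extended lists. Of the 25 lists, 6 kept only planned tags (ATP synthase, the *nuo* operon, cytochrome oxidases, the DosR block, fatty acid and mycolic acid synthesis, and the division cluster), 8 combined planned tags with symbols, and 11 rest on symbols or gene type alone. Of the planned lists 6 could not be built, and 3 were added (amino acid synthesis, nucleotide synthesis and protein export).

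The alternatives were DESeq2 1.42.0 (adjusted p left undefined for 1781 genes), limma-voom, RLE, total-count and upper-quartile scaling, cyclic loess, 2 other count filters, rRNA rows kept, and each library left out. Alternatives added after seeing the data left out *ssrA*, used robust shrinkage or voom quality weights, or left out active replicate 3 and dormant replicate 9 together. Detection was also compared after thinning the counts outside rRNA to the smallest such total. The test was run on simulated data with 6033 genes drawn at the real means, library sizes and spread, 200 of them changed, in 5 runs. It recovered 0% of 2-fold and 4.2% of 8-fold changes with a mean of 1 false call, and gave 99.8% of the 8-fold changes the right sign. With the real dispersion divided by 10 it recovered 49.8% and 100%, with a mean of 11.2 false calls. A list of 30 genes shifted 2-fold was called by camera in 5 of 5 runs, and 0 of 50 unchanged lists were called. The simulated genes were drawn independently of each other, whereas ribosomal protein genes had an estimated correlation of 0.352. These runs therefore cannot show how often camera calls unchanged lists of correlated genes.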

Results

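RNA was measured in the membrane fraction of *Mycolicibacterium smegmatis* MC2 155, a fast-growing saprophytic mycobacterium, in an actively growing and a dormant state. The fraction was pelleted by ultracentrifugation from lysed cells, so the values describe RNA that sedimented with membranes and not the RNA of whole cells. The 3 libraries of active cells (replicates 1, 3 and 7) came from cells grown in standard Sauton medium and harvested before stationary phase. The 3 libraries of dormant ovoid cells (replicates 2, 4 and 9) were taken from aged cultures in an acidified version of that medium that had been kept without shaking at room temperature. The libraries held 13636081, 5333195 and 14690576 counts in active replicates 1, 3 and 7, and 11473374, 11212255 and 6078676 in dormant replicates 2, 4 and 9. The labels do not say whether the libraries came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

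The comparison of the 2 states first asked what kinds of RNA the libraries held. Ribosomal RNA took 64.6% ± 26.7 of the counts in dormant cells and 13.7% ± 6.19 in active cells (SD, n = 3 each). Every dormant library (58.0%, 41.7% and 94.0% for replicates 2, 4 and 9) lay above every active library (16.5%, 6.56% and 17.9% for replicates 1, 3 and 7). The tmRNA gene *ssrA* (MSMEG_2093), whose product rescues stalled ribosomes, took 0.789%, 6.94% and 1.25% of the counts outside rRNA in active replicates 1, 3 and 7 and 5.93%, 54.1% and 44.9% in dormant replicates 2, 4 and 9. Transfer RNAs took 0.0175% ± 0.00738 of these counts, *ssrA* included, in active and 0.00804% ± 0.0039 in dormant cells (SD, n = 3 each). The groups overlapped, with 0.00898% to 0.0221% in active and 0.00354% to 0.0104% in dormant libraries (exact permutation p = 0.3).

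The rRNA difference of 50.9 percentage points had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give, and the difference in the *ssrA* share had an exact permutation p of 0.2. As a share of all counts, *ssrA* differed by 9.52 percentage points (exact permutation p = 0.5), and by −0.122 without dormant replicate 4. As a gene among the others, *ssrA* (MSMEG_2093) had a log2 fold change of 4.65 ± 1.66 (SE) with an edgeR adjusted p of 0.251. The 10 most abundant genes outside rRNA took 45.1% ± 23.7 of those counts in dormant and 10.0% ± 2.85 in active libraries (SD, n = 3 each, exact permutation p = 0.1). Much of the dormant share was *ssrA* again. In dormant replicates 4 and 9 *ssrA* alone took 54.1% and 44.9%, and the 10 genes together 61.6% and 55.7%. In dormant replicate 2 the 10 genes took 17.9%, with *ssrA* at 5.93%. Genes with at least 10 counts numbered 4500 ± 2251 in dormant and 6280 ± 198 in active libraries (SD, n = 3 each, exact permutation p = 0.1), a difference of −1780 that was −480 without dormant replicate 9. That library kept 367259 counts outside rRNA, against 4819110 to 12059943 in the other 5, so that 3 counts in it correspond to 14.2 CPM, the unit of TMM-normalised abundance used for single genes. After thinning all libraries to that number of counts outside rRNA, 2361 ± 631 genes in dormant and 3183 ± 200 in active libraries reached 10 counts (SD, n = 3 each, exact permutation p = 0.2). The thinned counts still held *ssrA*, so depth for the other genes was not made equal. Dormant replicate 2 kept 3081 genes, within the active range of 2988 to 3387, and dormant replicates 4 and 9 kept 2102 and 1901.

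**Figure D1:**
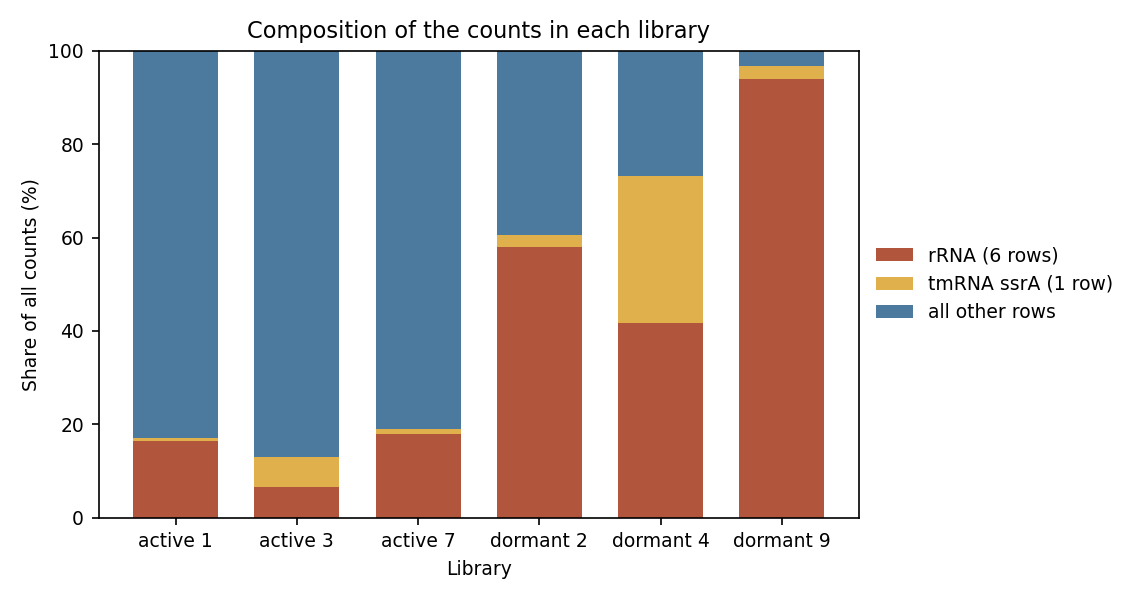
Share of all counts (percent, vertical axis) in rRNA, in the tmRNA *ssrA* and in all other rows for each of the 6 libraries. The rRNA part is 6.56% to 17.9% in the 3 active libraries and 41.7% to 94.0% in the 3 dormant libraries.

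The second question was which transcripts differed in abundance between dormant and active cells. Transcripts of 12 genes were called higher in dormant cells, all by at least 3.28 on the log2 scale. Among them was *derK* (MSMEG_3271), encoding D-erythrulose kinase, at 1005 ± 603 CPM in dormant and 47.8 ± 6.36 CPM in active cells (SD, n = 3 each). The adjacent *derI1* (MSMEG_3272), encoding D-erythrulose-4-phosphate isomerase, stood at 161 ± 44.6 and 8.78 ± 1.71 CPM (SD, n = 3 each). Both enzymes act in the breakdown of the sugar alcohols erythritol and threitol, and the neighbouring MSMEG_3270 (log2 fold change 4.34 ± 0.66, SE) rose with them. The largest rise was that of MSMEG_6813, from 4.35 ± 1.57 to 597 ± 431 CPM (SD, n = 3 each), a log2 fold change of 7.08 ± 0.88 (SE), followed by MSMEG_3012 (6.81 ± 1.03), MSMEG_6668 (5.71 ± 0.88), MSMEG_1623 (5.20 ± 0.81), MSMEG_1511 (4.59 ± 0.66) and MSMEG_5039 (4.59 ± 0.69). Single libraries carried part of some of these values. Without dormant replicate 4 MSMEG_3012 stood at 5.27, below MSMEG_6668 (5.78) and MSMEG_1623 (5.50), and without dormant replicate 9 MSMEG_6813 stood at 6.44, MSMEG_6668 at 4.84, MSMEG_1623 at 4.18 and *derK* at 3.80.

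The remaining risen genes were MSMEG_2180 (log2 fold change 4.54 ± 0.59, SE), MSMEG_6428 (3.49 ± 0.55) and MSMEG_6468 (3.28 ± 0.52), which follows the *dps* gene MSMEG_6467. The annotation used gives no symbol for the 10 genes other than *derK* and *derI1*. Each of the 12 was higher in 3 of 3 dormant libraries than in every active library, and their adjusted p-values from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.0462 to 0.0475. None of the 6033 genes tested was called lower in dormant cells in that test, against 111 with DESeq2 and 0 with limma-voom. On simulated data at the real spread this test recovered 4.2% of 8-fold and 0% of 2-fold changes. With a mean of 1 false call per run, some of the 12 may be false, and real changes may be missed in either direction. At an unadjusted p under 0.05, 525 genes were higher and 432 lower. These are 957 genes together. Setting active replicates 1 and 7 with dormant replicate 2 against the other 3 libraries gave 841, and the other 8 splits of the libraries gave 131 to 441. Over all genes tested, 23.2% separated the groups completely (740 with all dormant libraries above and 660 with all below). Averaged over all splits of the libraries this share is 10%. Genes vary together and the share was not counted for the other splits, so an excess over them was not tested.

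These counts moved with the settings. DESeq2 called 229 genes higher and limma-voom 36. Scaling to total counts called 26 higher and 60 lower, against 12 and 0, and RLE size factors called 0 (lowest adjusted p 0.0546). Leaving out a library gave 0 calls without active replicate 7, dormant replicate 4 or dormant replicate 9, 2 higher without dormant replicate 2, 18 higher and 18 lower without active replicate 1, and 99 higher and 2 lower without active replicate 3. Without both active replicate 3 and dormant replicate 9 there were 0 calls, and all 12 genes kept a positive fold change in all of these settings.

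**Figure D2:**
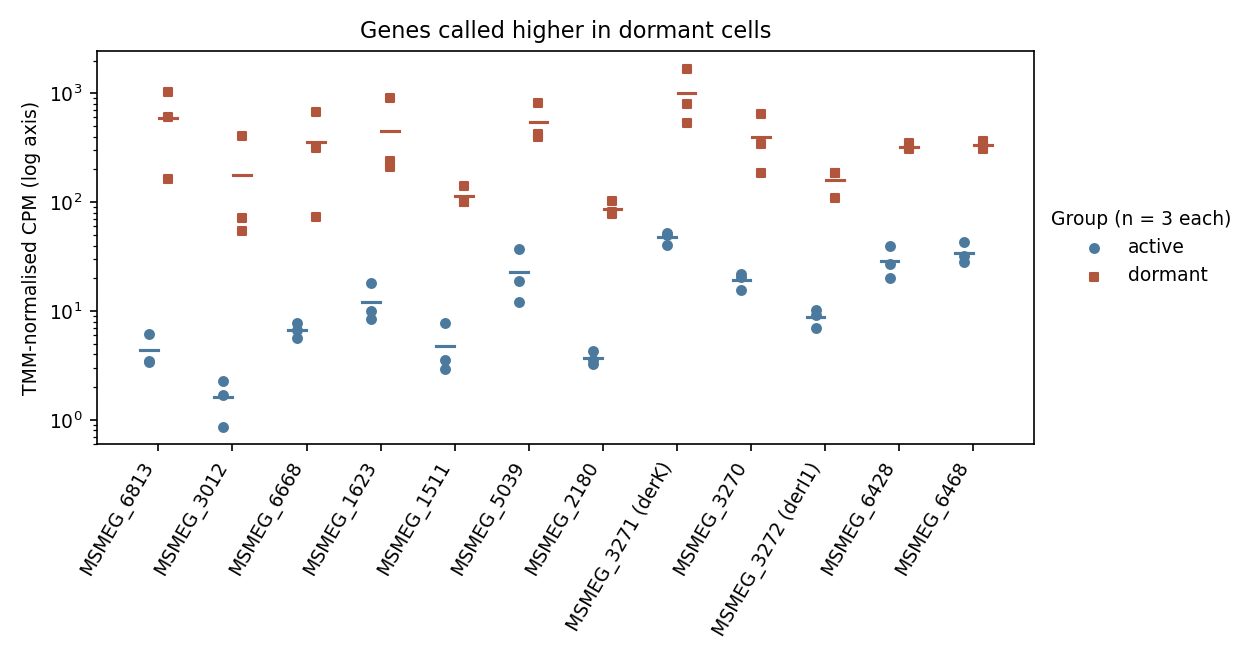
TMM-normalised CPM (log axis) in each library for the 12 genes called higher in dormant cells, with circles for active and squares for dormant libraries and a line at each group's mean (n = 3 each). In each gene the 3 dormant libraries lie above the 3 active ones, from a mean of 4.35 against 597 CPM for MSMEG_6813 to 34.3 against 334 CPM for MSMEG_6468.

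Genes for ribosomal proteins and for aminoacyl-tRNA synthetases were lower as groups in dormant cells in the camera test with a preset correlation (adjusted p = 5.37e-07 and 0.0414). Neither call held with an estimated correlation (adjusted p = 0.836 for each). Of 51 genes for ribosomal proteins, 50 had a negative log2 fold change, with a median of −0.92 against −0.12 over all genes tested. Examples were *rpsS* (from 613 ± 341 to 145 ± 18.4 CPM), *rpsM* (540 ± 175 to 139 ± 68.3 CPM) and *rpsB* (1297 ± 391 to 687 ± 99.6 CPM; SD, n = 3 each), and the exception was *rplT* at 0.51 ± 0.55 (log2 fold change, SE). All 16 aminoacyl-tRNA synthetase genes, whose products charge tRNAs, had negative values (median −0.80), from *trpS* at −1.40 ± 0.62 to *pheS* at −0.11 ± 0.54, with *alaS* at −0.28 ± 0.53 and *leuS* at −0.47 ± 0.58 (SE). The 16 genes for translation factors and RNA polymerase were not called (median −0.29, camera adjusted p = 0.914), and *rpoB* (MSMEG_1367) and MSMEG_1368 stood at 1.19 ± 0.63 and 1.27 ± 0.68 (log2 fold change, SE). The list of tRNA genes had 10 members with enough counts, a median of 0.09 and a camera adjusted p of 0.914 with the test pointing down. From its 4 planned tags alone, the list of translation factors and RNA polymerase had a median of 0.57, opposite in sign to the extended list, and a camera adjusted p of 0.637.

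Genes for ATP synthase, the division and cell wall cluster and trehalose were lower as groups in the same test (adjusted p = 0.0417 for each). These calls did not hold with an estimated correlation either (adjusted p = 0.836 for each). The 8 genes of the F1Fo ATP synthase operon were all negative (median −0.93), with *atpA* at 831 ± 312 CPM in active and 305 ± 123 CPM in dormant cells and *atpD* at 611 ± 348 and 339 ± 88.0 CPM (SD, n = 3 each). In the division and cell wall cluster 15 of 17 genes were negative (median −0.87). Among them were *ftsZ*, encoding the division ring protein (−1.86 ± 0.80), and *murC* (−1.79 ± 0.82), while *wag31*, encoding a polar growth protein, stood at 0.37 ± 0.50 (log2 fold change, SE). The *ftsZ* value was −2.99 without dormant replicate 2 and −0.87 without active replicate 7. Of 4 genes of trehalose metabolism, *treS* (−3.07 ± 1.00), *treY* (−2.29 ± 0.62) and *treZ* (−1.55 ± 0.53) were negative and *otsB* stood at 0.22 ± 0.83 (log2 fold change, SE). The *treS* value rested largely on active replicate 3, at 3123 CPM against 150 and 524 CPM in active replicates 1 and 7.

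The lists were planned from locus tags and product names, with tags alone as the fallback, and gene symbols were used in place of product names after the annotation was seen. With these extended lists the camera test with a preset correlation between genes gave adjusted p-values of 5.37e-07 for ribosomal proteins, 0.0414 for aminoacyl-tRNA synthetases and 0.0417 for each of ATP synthase, the division cluster and trehalose. From the planned tags alone 13 lists could be tested, and ATP synthase and the division cluster passed (camera adjusted p = 0.0445 for each, and 0.96 for each with an estimated correlation), while ribosomal proteins, synthetases and trehalose had no planned tags. In the extended lists, with an estimated correlation none of these 5 calls held (adjusted p = 0.836 for each), and the rotation test fry, which asks whether a list moves one way on balance, gave adjusted p-values of 0.236 to 0.242. No member of the 25 lists passed the test over all genes. Adjusted over the list alone, 3 trehalose genes (*treS*, *treY* and *treZ*) fell, *clpB* among the chaperones and *msrB* (MSMEG_2784) in oxidative stress defence rose, and 0 genes of the other 22 lists passed. The ribosomal protein call held in each fit without a library (highest adjusted p 0.00248), whereas the other 4 calls were each lost without active replicate 7 (adjusted p 0.0864 to 0.112) and without dormant replicate 4 (0.0527 to 0.236). Without active replicate 1, ATP synthase (0.0578), synthetases and the division cluster (0.123 for each) were lost, and without dormant replicate 2 ATP synthase (0.0567) and trehalose (0.107). Trehalose was also lost without active replicate 3 (0.0984) and without dormant replicate 9 (0.103). The medians moved as well, to −1.46 for the division cluster and −1.21 for synthetases without dormant replicate 2 to −0.61 for ATP synthase without active replicate 7 and to −1.30 for trehalose without active replicate 3. Scaling to total counts also ended these 4 calls (adjusted p = 0.0652 for each) and not that of ribosomal proteins. Without active replicate 3 and dormant replicate 9 together, ribosomal proteins had an adjusted p of 2.84e-06 and trehalose 0.211.

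**Figure D3:**
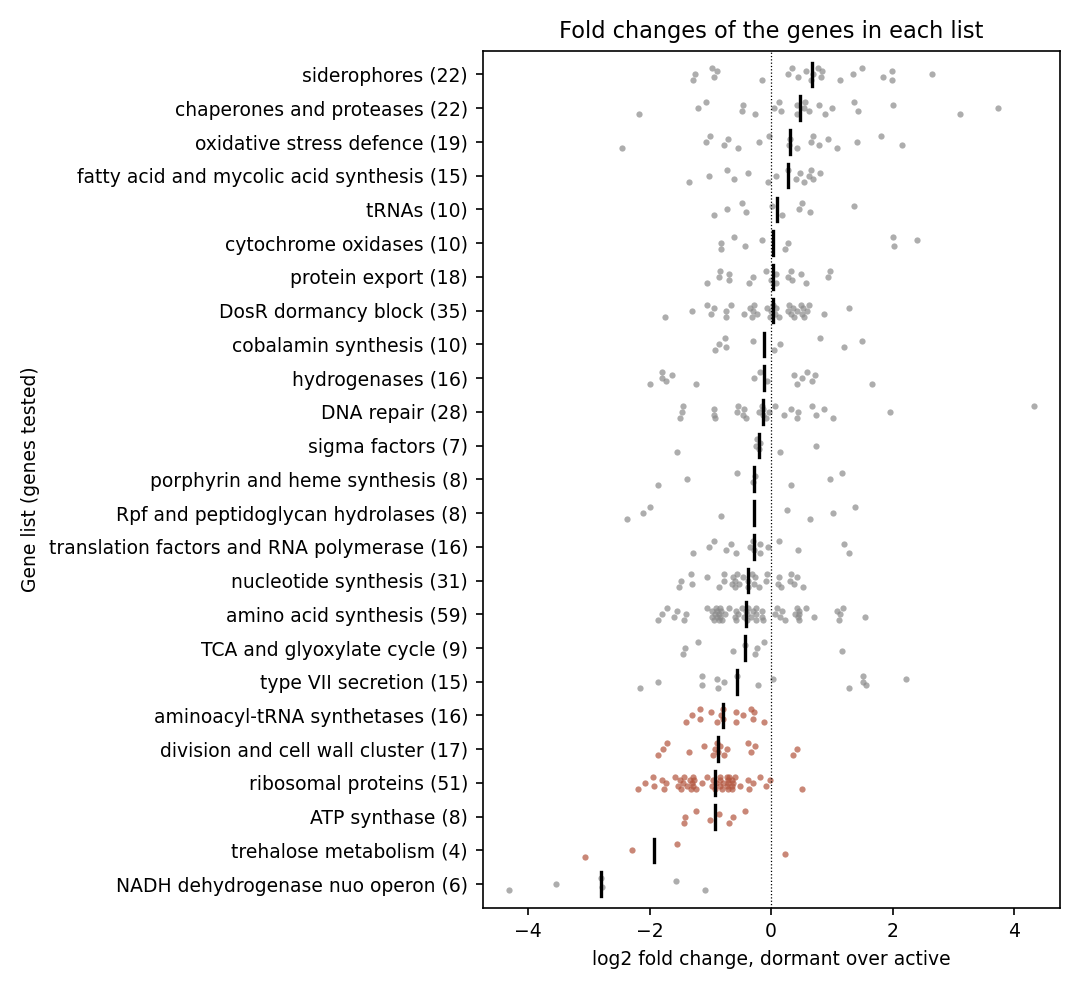
Log2 fold changes (dormant over active, horizontal axis) of the tested genes of each of the 25 lists (rows, with the number of genes tested), with a bar at each list's median. The 5 lists in red passed the camera test with a preset correlation, all with a negative median, and the adjusted p was 0.836 for each with an estimated correlation.

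Stress genes gave individual high values and no group call. Of 22 chaperone and protease genes 16 were positive (median 0.48, camera adjusted p = 0.118), led by *clpB*, encoding a disaggregase, at 198 ± 51.4 CPM in active and 2621 ± 2378 CPM in dormant cells (SD, n = 3 each). Its log2 fold change was 3.73 ± 0.78 (SE, edgeR adjusted p = 0.0837). The protease genes *lon* (3.11 ± 1.07) and *clpC1* (1.43 ± 0.68) and *dnaK* (1.00 ± 0.77) were also positive, and the chaperonin copy *groL* MSMEG_1978 stood at −2.17 ± 0.83 (log2 fold change, SE). The *dnaK* value rested on dormant replicate 4, at 7396 CPM against 1608 and 1681 CPM in dormant replicates 2 and 9, and was −0.12 without it. The *lon* value likewise came largely from that library, at 2675 CPM against 304 and 280 CPM. In oxidative stress defence (19 genes, median 0.31, camera adjusted p = 0.401), the methionine sulfoxide reductase genes *msrA* and *msrB* (MSMEG_2784) stood at 1.81 ± 0.52 and 2.15 ± 0.53, and *katG* (MSMEG_3461) at 0.31 ± 0.57 (log2 fold change, SE). Of 22 genes for siderophores, molecules that capture iron, 16 were positive (median 0.67, camera adjusted p = 0.0518), including *mbtM* (2.64 ± 0.88) and *mbtB* (1.85 ± 0.53, SE). This list passed without active replicate 1 (camera adjusted p = 0.0147) and without dormant replicate 4 (0.0059), while with all libraries and an estimated correlation its adjusted p was 0.836. The chaperone median was 0.22 without dormant replicate 2, and that of oxidative stress defence was 0.11 without dormant replicate 4 or dormant replicate 9 and 0.13 without active replicate 7. Scaling to total counts lowered the median of all genes to −0.91 and the medians of these lists to −0.35, −0.53 and −0.19. All 8 lists with a positive median turned negative under that scaling, so a positive sign here is relative to the other transcripts.

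The 35 genes of the DosR dormancy block, named for the regulator of the hypoxic dormancy response, were not called as a group. Their median log2 fold change was 0.03 and their mean −0.07, the camera test pointed up with an adjusted p of 0.914, and 19 were positive and 16 negative. The median was negative without active replicate 7 (−0.21), dormant replicate 2 (−0.25), dormant replicate 4 (−0.09) or dormant replicate 9 (−0.05). The regulator gene *devR* (annotated as *dosR*, MSMEG_5244) stood at 1199 ± 293 CPM in active and 1541 ± 351 CPM in dormant cells. For *hspX* (MSMEG_3932), encoding a small heat shock protein, the values were 1482 ± 1216 and 1626 ± 496 CPM (SD, n = 3 each). The *hspX* log2 fold change was 0.13 ± 0.73 (SE). It was 0.98 without active replicate 1 and −0.32 without dormant replicate 2 or active replicate 7. The abundant block members MSMEG_5245 and MSMEG_5246 stood at 0.60 ± 0.65 and −0.23 ± 0.70 (log2 fold change, SE).

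Respiratory genes gave values of either sign and no group call. In the cytochrome oxidase list (10 genes, median 0.04, mean 0.41, camera adjusted p = 0.401) the bd oxidase genes had positive values. These were *cydB* at 2.40 ± 0.89 and MSMEG_3233 at 2.03 ± 0.77 (log2 fold change, SE). By contrast, *qcrB* of the bcc complex stood at 0.22 ± 0.63 and *ctaC* of the aa3 oxidase at −0.62 ± 0.55 (log2 fold change, SE). The median of this list changed sign without active replicate 3 (−0.30), dormant replicate 2 (−0.22) or dormant replicate 9 (−0.03). The 6 tested genes of the *nuo* operon for the proton-pumping NADH dehydrogenase had a median of −2.80 (camera adjusted p = 0.179), carried by active replicate 3. There *nuoD* stood at 108 CPM, against 1.73 to 4.75 CPM in the other 5 libraries, and *nuoF* at 135 CPM. Without active replicate 3 the median was 0.22, and the list passed without active replicate 1 (camera adjusted p = 0.0146), active replicate 7 (0.0464) or dormant replicate 9 (0.0325). With all libraries and an estimated correlation between its genes, which was 0.931, its adjusted p was 0.945. Hydrogenase genes (16, median −0.12, camera adjusted p = 0.914) held the pair MSMEG_2262 and MSMEG_2263 at 1433 ± 1230 and 4032 ± 2748 CPM in active and 462 ± 655 and 1006 ± 1382 CPM in dormant cells (SD, n = 3 each). Dormant replicate 2 carried the dormant means, at 1217 and 2601 CPM, and without it the log2 fold changes were −4.33 for MSMEG_2262, against −1.63 ± 1.10 (SE) with it, and −4.48 for MSMEG_2263 (edgeR adjusted p = 0.14 and 0.129). From its 8 planned tags alone this list had a median of 0.16 with the test pointing down (camera adjusted p = 0.918). The 9 genes of the citric acid and glyoxylate cycles had a median of −0.44 (camera adjusted p = 0.487). Of these, 8 were negative, among them *sucB* at −0.12 ± 0.53, and only MSMEG_3640 was positive, at 1.16 ± 0.66 (log2 fold change, SE).

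Biosynthetic lists did not pass. The medians were −0.42 for 59 amino acid synthesis genes and −0.39 for 31 nucleotide synthesis genes (camera adjusted p = 0.168 for each), with *glnA* (MSMEG_4290) at 0.46 ± 0.64 and *metH* at 0.42 ± 0.56 (log2 fold change, SE). Both lists passed without active replicate 3 (camera adjusted p = 0.0069 and 0.0072), while with all libraries and an estimated correlation the adjusted p was 0.945 for each. The *nrdE* copies MSMEG_1019 and MSMEG_2299, at −0.65 ± 0.58 and −0.63 ± 0.59 (SE), had almost equal counts in each library and are uncertain, since reads may be shared between them. Fatty acid and mycolic acid synthesis (15 genes, median 0.28, camera adjusted p = 0.914) included *kasA* at 0.66 ± 0.77 and MSMEG_4757 at 0.08 ± 0.74. Porphyrin and heme synthesis (8 genes, median −0.28, camera adjusted p = 0.914), examined because these dormant cultures change colour, held *hemA* (−0.26 ± 0.52), *hemB* (1.17 ± 0.48) and *hemQ* (−1.38 ± 0.69). Cobalamin synthesis (10 genes, median −0.12, mean 0.01, camera up with adjusted p = 0.959) held *cobN* at 1.49 ± 0.73 and *cobO* at −0.77 ± 0.62.

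For the cell surface and the genome the lists also did not pass. Medians that changed sign without a library were those of Rpf and peptidoglycan hydrolases (0.32) and hydrogenases (0.55) without active replicate 1, protein export without active replicate 3 (−0.19) or dormant replicate 2 (−0.24), sigma factors without active replicate 3 (0.02), tRNAs without dormant replicate 4 (−0.28) and cobalamin synthesis without dormant replicate 9 (0.13). Of 8 Rpf and peptidoglycan hydrolase genes (median −0.28, camera adjusted p = 0.709), *ripA* (−2.11 ± 0.73) and *ripB* (−2.37 ± 0.88) were negative and *ripC* (0.26 ± 0.72) positive (log2 fold change, SE). Type VII secretion (15 genes, median −0.56, mean −0.10, camera adjusted p = 0.914) held *eccA1* (−1.15 ± 0.67) and *eccCa* (−0.87 ± 0.50). Protein export (18 genes, median 0.04, mean −0.05, camera down with adjusted p = 0.914) held *secA* at 705 ± 20.9 CPM in active and 1051 ± 66.9 CPM in dormant cells (SD, n = 3 each; log2 fold change 0.57 ± 0.49, SE, edgeR adjusted p = 0.585) and *ffh* at −0.69 ± 0.57. DNA repair (28 genes, median −0.14, mean 0.02, camera down with adjusted p = 0.914) held *uvrB* at 319 ± 104 and 1231 ± 67.7 CPM (SD, n = 3 each; log2 fold change 1.95 ± 0.54, SE, edgeR adjusted p = 0.156) and *uvrA* at 0.33 ± 0.51.

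A fixed panel of genes linked to dormancy gave no call. Besides *ftsZ*, the lowest values of the panel were those of 2 nucleoid protein genes, with *dps* (MSMEG_6467) at −2.83 ± 0.97 and *hupB* (MSMEG_2389) at 1340 ± 456 CPM in active and 369 ± 218 CPM in dormant cells (SD, n = 3 each; log2 fold change −1.85 ± 0.62, SE; edgeR adjusted p = 0.238 and 0.233). The *dps* value spread widely within active cells, at 210, 5521 and 2260 CPM for replicates 1, 3 and 7. The *hupB* value was −2.57 without dormant replicate 2 and −1.54 without active replicate 3. The ribosome hibernation gene *hpf* (MSMEG_1878) stood at 1.22 ± 0.73, and the isocitrate lyase gene *aceA* (MSMEG_0911) at −0.23 ± 1.06 (log2 fold change, SE). The *hpf* value was 2.13 without active replicate 1 and 0.77 without active replicate 7. The *aceA* value rested on active replicate 3, at 897 CPM against 47.6 and 60.4 CPM in active replicates 1 and 7, and was 2.39 without that library (edgeR adjusted p = 0.107) and 0.07 without dormant replicate 2. In all, 13 of the 64 genes of the naming rule, none of them called, changed sign in a fit without a library. Of the sigma factors (7 genes, median −0.20, camera adjusted p = 0.914), *sigA* and *sigB* stood at −0.25 ± 0.55 and −0.23 ± 0.68 and *sigF* (MSMEG_1804) at −1.55 ± 0.73. The adenylyl cyclase gene MSMEG_4279 stood at 0.02 ± 0.74, with 8.47 to 13.7 CPM in 5 libraries and 0 counts in dormant replicate 9, which allows up to 14.2 CPM.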

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

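The settings without *ssrA*, with robust shrinkage, with voom quality weights, with counts outside rRNA thinned, and without both active replicate 3 and dormant replicate 9 were chosen after seeing the data. The 12 genes higher in dormant cells kept their sign in all 19 alternatives, with a lowest log2 fold change of 2.49, but each passed the threshold in only 8 to 14 of them. The number of genes higher was 229 with DESeq2, 36 with limma-voom, 0 with RLE factors, 26 with total counts, 23 with cyclic loess, 116 with voom quality weights and 0 without active replicate 3 and dormant replicate 9, and 0 to 99 with a library left out. Genes lower numbered 111 with DESeq2, 60 with total counts and 1 with voom quality weights, against 0, and 0 to 18 with a library left out. Genes changed at least 2-fold numbered 340 with DESeq2, 36 with limma-voom, 0 with RLE factors, 86 with total counts, 23 with cyclic loess, 117 with voom quality weights and 0 without both libraries, and 0 to 101 with a library left out. With RLE factors the 12 genes had an adjusted p of 0.0546, so the loss there is a small move across the threshold. Gene lists called numbered 2 with the planned tags alone, because ribosomal proteins, synthetases and trehalose have none, 1 with total counts, 0 with an estimated correlation and 0 with fry, against 5, and 2 to 6 with a library left out. The group difference in the share of the 10 most abundant genes was 58.5 percentage points with rRNA rows kept, because rRNA rows then fill that share, against 35.1. The cause of the other moves was not tested, except that fits without a library have fewer samples. The median log2 fold change of all genes was −0.12, and −0.91 with total counts, −0.24 with RLE factors and −0.04 with cyclic loess. For the 64 genes of the naming rule, 1097 of 1212 alternative values kept direction and side of the threshold, 36 lost and 9 gained a call, 0 reversed a call and 70 changed the sign of an uncalled value (16 with total counts). For lists the numbers were 193 of 263 kept, 30 lost, 9 gained and 31 uncalled sign changes (8 with total counts). Depth limits dormant replicate 9 most, where 2475 rows outside rRNA had 0 counts.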

Other observations

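The tests of scaling, of dormant replicate 9, of exchanged labels and of other splits, the count of gene runs and the check of the mixture estimate on dormant replicate 4 were chosen after the results were seen.

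Neighbouring genes had values in the same direction beyond the 12 called. There were 32 runs of at least 4 consecutive locus tags with an unadjusted p under 0.05 in the same direction, 17 higher and 15 lower in dormant cells. In 1000 shuffles of gene positions the mean was 0.354 runs and the highest number 3, although co-transcribed genes are not independent. Shuffling breaks up such genes, so any source of variation between libraries could give more runs in the real order. Runs were not counted for other splits of the libraries, so their number does not tie them to dormancy. The longest run, of 9 genes, went from *eltD* (MSMEG_3265, log2 fold change 3.43 ± 0.67, SE) to MSMEG_3273 (1.98 ± 0.73) and included *derK* and *derI1*. The flanking MSMEG_3264 and MSMEG_3274 stood at 0.54 ± 0.56 and −0.64 ± 0.77. A run of 7 genes ended in *dthD* (MSMEG_3607, 1.80 ± 0.65), which encodes D-threitol dehydrogenase and so, like *derK*, belongs to the use of sugar alcohols. Its members had adjusted p-values of at least 0.154.

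Among the other higher runs, *kdpA* (MSMEG_5392) and *kdpB* (MSMEG_5393), encoding a high-affinity potassium pump, stood at 4.91 ± 0.91 and 3.96 ± 1.19 (log2 fold change, SE). Both were highest in dormant replicate 9, at 271 and 309 CPM, against 52.9 and 65.0 CPM in replicate 2 and 67.2 and 85.7 CPM in replicate 4. The propionate genes *prpD* (MSMEG_6645) and *prpB* (MSMEG_6646) stood at 3.78 ± 0.83 and 3.32 ± 0.69, and the glycerol kinase gene *glpK* (MSMEG_6759) at 2.62 ± 0.80. In dormant replicate 9 *prpD* had 1 count and *prpB* 3 counts, so these 2 values rest mainly on dormant replicates 2 and 4. Among the lower runs were the histidine degradation genes *hutI* (MSMEG_1182) and *hutH* (MSMEG_1183) at −4.26 ± 1.30 and −3.73 ± 1.18, and *usfY* (MSMEG_1769) at −3.82 ± 1.02. The lower values rested largely on active replicate 3, where *hutH* had 280 CPM against 15.9 and 26.2 CPM in active replicates 1 and 7 and *usfY* 1139 CPM against 46.0 and 285 CPM. Among DNA repair genes *mutY* (MSMEG_6083) had the highest value, 4.32 ± 1.26, with 627 ± 912 CPM in dormant and 31.7 ± 21.4 CPM in active cells (SD, n = 3 each), carried by dormant replicate 4 at 1680 CPM. None of these passed the edgeR threshold (adjusted p 0.0642 to 0.209). Of the type VII secretion genes, *eccD* (MSMEG_0623) stood at 2.22 ± 0.66 and *eccE* (MSMEG_0082) at −2.15 ± 0.88, and neither passed (edgeR adjusted p = 0.188 and 0.284).

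The first pattern is the set of 12 genes higher in dormant cells. The choice of scaling cannot be excluded as the source of these calls. Over 6 other scalings the lowest log2 fold change of the 12 genes was 2.49, so their direction did not depend on scaling. This was a weak test, because the genes had large changes to begin with. Total counts moved the median of all genes only from −0.12 to −0.91. The calls did depend on scaling: RLE factors ended every call, and total counts called 26 genes higher and 60 lower. Dormant replicate 9 alone did not carry the direction. Without that library the lowest value was that of MSMEG_6468, at 3.28 (95% interval from 2.15), against 3.28 ± 0.52 (SE) before. Other genes moved either way, such as MSMEG_1623 from 5.20 to 4.18 and MSMEG_3012 from 6.81 to 7.16. Every call ended (edgeR adjusted p 0.14 to 0.171) with 5 libraries left. The genes were chosen with these same libraries, which favours a positive value in this test. The real split was the only 1 of 10 splits of the libraries with as many calls (12 against at most 0 in the others), but the split with dormant replicate 2 beside active replicates 1 and 7 had 841 genes at an unadjusted p under 0.05 against 957, and 10 splits are too few for a share under 0.05. A rise with dormancy stays open as a hypothesis and may include effects of medium and culture age, which differ between the groups in the same way.

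The second pattern is the higher rRNA share in dormant libraries. A different yield of rRNA removal stays open. The ratio of 23S to 16S counts was at least 14.2 in every library. Equal numbers of the molecules, as in ribosomes, would give a count ratio near that of their lengths, which is far lower. The rRNA shares, those of the active libraries included, therefore cannot be read as rRNA levels in cells. The ratio was 71.5 ± 35.1 in dormant and 25.9 ± 10.5 in active libraries (SD, n = 3 each, exact permutation p = 0.1). The groups barely separated in that ratio, with 34.3 in dormant replicate 4 and 34.2 in active replicate 1, and the difference of 45.6 was 29.2 without dormant replicate 9. The labels name no removal step. As sources of the group difference, removal, loss of mRNA in dormant cells and a different make-up of the membrane fraction cannot be told apart.

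The third pattern is that dormant replicate 2 resembled active replicates 1 and 7 (Pearson r of log CPM across genes 0.912 and 0.878) at least as closely as dormant replicates 4 and 9 (0.859 and 0.796), the first of these close to the value with active replicate 7. Dormant replicate 9, with 367259 counts outside rRNA, stood apart from every library (0.604 to 0.796), and active replicate 3 stood apart from active replicates 1 and 7 (0.735 and 0.768); genes are not independent replicates. Exchanged labels are argued against by genes at least 8-fold higher in dormant replicates 4 and 9 than in active replicates 1 and 7: over these 69 genes active replicate 3 lay at a median of 0.0727 of the way to the dormant level (interquartile range 0.0206 to 0.369), although over 25 genes lower in the dormant pair it lay at 0.907 (0.265 to 0.958), as a dormant library would. Dormant replicate 2 lay at 0.355 (0.206 to 0.664) over the same 69 genes and at 0.553 (0.499 to 0.707) over the 25, which a mixture with active-type RNA could give. The same measure put dormant replicate 4 at 0.669 (0.499 to 1.06) over 45 genes chosen without it, so ranges overlap and a mixture, an earlier stage of dormancy and ordinary spread cannot be told apart.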
